A study of Danio rerio with 2 samples.

How the data were processed

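Whole zebrafish larvae at 7 days post fertilization, per the sample labels, were dissociated and profiled by droplet single-cell RNA sequencing with the 10x Genomics Chromium 3′ method. There was 1 library of wild-type larvae (WT) and 1 library of larvae heterozygous for a cftr mutation (cftr_het). The series' design text gives the age as 7 hours, while the sample labels give days. The genotype used here is that of the sample labels, although the deposited material of the second library also carries the word knockout. How many larvae went into each library is not given in the sources used here.

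The deposited matrices hold whole-number UMI counts per gene and barcode, written by Cell Ranger 7.0.0 per the file headers. A UMI, or unique molecular identifier, marks 1 captured transcript molecule. The submitters' processing notes also list STAR and Seurat 4.0.1, without their roles, and name only human and mouse genome builds. Of the feature identifiers, 28988 matched the name table used here. All but 23 of the feature identifiers belong to zebrafish genes, so the counts cannot stem from those builds. The zebrafish build and annotation release are not given in the sources used here. The lowest UMI total of a deposited barcode was 500 in both libraries. Features that share a symbol were summed, which concerned 520 symbols and left 31392. Reads shared by near-identical gene copies could have been split by the upstream counting, so members of the ferritin, globin, myosin and protease families are uncertain one from another.

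Barcodes with at least 200 genes, 500 UMIs and at most 20% of UMIs on mitochondrially encoded genes were taken on, 7914 in WT and 7969 in cftr_het. Doublets were marked in each library from simulated doublets, at an assumed rate of 0.8% per 1000 cells. This removed 501 WT and 508 cftr_het barcodes and left 7413 and 7461 cells. Counts per 10000 UMIs were log transformed after adding 1. The 2000 most variable genes and 30 principal components of both libraries together gave a graph of 15 nearest neighbours. Leiden clustering at resolution 1 gave 48 clusters. No batch integration was used, because library and genotype coincide.

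Cell classes were named from marker genes fixed before the data were examined. A cluster took a class name if at least 3 markers of that class were detected in 20% of its cells and stood above 2-fold over all other cells, and the class with the highest mean fold was taken. It stayed unnamed where its 10 or 15 leading genes held more markers of another class, or where it was shallow and had no leading marker. By these rules 37 clusters received 23 class names and 11 stayed unnamed. A class name such as neuron means cells like that type by their markers, since no cell annotation was used here.

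UMIs were summed per gene, library and class and expressed as CPM, the count scaled to a total of 1000000 UMIs. The log2 ratio of CPM, cftr_het over WT, was computed with a prior of 0.5 UMIs added to each count. With 1 library per group there is no test, and no p-value or standard error is given, since cells are not replicates. Intervals are 95% intervals: exact Poisson limits for a summed count, exact Clopper-Pearson limits for a share, and exact conditional binomial limits for a ratio. For the median of a gene list they come from 400 Poisson redraws of its counts. All of these cover counting error only, not the spread between larvae, dissociations or libraries. Where a gene had no UMI in a library, the fold is a lower bound against a floor of 3 UMIs in that library's class.

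Genes were named by a rule fixed before the data were examined. In neurons, a gene needed at least 50 UMIs over both libraries, a CPM of at least 20 in 1 library, the same direction in the neuron clusters with at least 20 of its UMIs, and an interval of the ratio that excluded 1. Its CPM in the class also had to reach 0.1 of its highest CPM in any other class, and otherwise it was set apart as possible background. The 12 highest and 12 lowest such genes were named, with 3 possible background genes each way. In each other class with at least 50 cells in each library the 3 highest and 3 lowest were named, and over all cells the 6 highest and 6 lowest with at least 200 UMIs. After the values had been seen, a further selection was added, of genes with UMIs in at least 20 cells of the library with the higher level, ranked without each gene's richest cell.

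There were 30 gene lists, 29 of them fixed by symbol and the cytosolic ribosomal proteins by a symbol pattern. A list's value is the median log2 ratio of its members with at least 20 UMIs. It is given with its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins, which describes these 2 libraries only. Members of a list can lie in the same few cells, which the random lists do not copy. A percentile can therefore be more extreme than it would be for independent members. From each list the 4 members with most UMIs and those whose interval excluded a 1.5-fold difference could be named. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, with fibroblasts as the class that should lack neuronal genes.

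The calculations were tested on simulated data for the comparison of cftr_het with WT in neurons. Counts were drawn from the pooled neuron means and real library sizes, with 50 genes changed at each of 4 sizes among 6046 genes. The intervals held the true ratio for 95.7% of the 6046 genes, and excluded 1 for 4.41% of 5846 unchanged genes. They excluded 1 in the right direction for 94.0% of genes raised 2-fold, 80.0% of genes lowered to 0.5, 100.0% of genes raised 4-fold and 98.0% of genes lowered to 0.25, each of 50. Of 100 unchanged lists of 25 genes, 5.0% fell outside the middle 95% of random lists, and 95.0% of 20 lists lowered by a log2 of 0.3 fell below percentile 2.5. The simulation has no spread between cells, so it does not cover genes carried by few cells.

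Before the data were examined, 22 alternatives were fixed, which vary the cell filter, doublets, clustering, depth, class definition, scaling, prior count, low counts, cluster weighting and free RNA. After the values had been seen 7 more were added, which leave out each gene's richest cell, weight neuron sub-clusters alike, leave out a GABAergic sub-cluster, leave out clusters of mostly 1 library, or name widely carried genes. The GABAergic sub-cluster was picked because its share of neurons fell most from WT to cftr_het, not for its transmitter. Scaling by TMM used edgeR 4.0.16 in R 4.3.3, with no test. The rest used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.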

Results

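The study asked how heterozygous loss of cftr, the gene of an epithelial chloride and bicarbonate channel, bears on the larval nervous system, in the setting of attention deficit-hyperactivity disorder. The WT library held 8399 deposited barcodes with 52149018 UMIs and the cftr_het library 8409 barcodes with 56261236 UMIs. The kept cells carried 44535304 UMIs in WT and 47712210 in cftr_het. The median kept cell had 3074 UMIs and 898 genes in WT and 3075 UMIs and 916 genes in cftr_het, so depth per cell was close to equal. Photoreceptors, chondrocytes, pigment cells, exocrine pancreas and erythroid cells were all present, differentiated types of a larva. There were no replicates, and every difference below is between these 2 libraries.

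Transcripts of cftr (ENSDARG00000041107) were rare in both libraries, and over all cells they did not differ detectably. WT cells held 32 cftr UMIs, or 0.719 CPM (0.491 to 1.01), and cftr_het cells 35 UMIs, or 0.734 CPM (0.511 to 1.02). The ratio of cftr_het to WT was 1.02, with an interval of 0.614 to 1.70. The cells with a cftr UMI numbered 21 in each library. In exocrine pancreas cells cftr had 8 UMIs in 5 WT cells and 2 in 2 cftr_het cells, a ratio of CPM of 0.0592 (0.00613 to 0.297), with 1028380 UMIs of all genes in WT and 4341642 in cftr_het. In neural progenitors or radial glia it had 2 UMIs in 1 WT cell and 9 in 2 cftr_het cells, a ratio of 8.63 (1.79 to 82.1). In endothelial cells it had 4 and 13 UMIs. The intervals count UMIs as independent, so with so few cells they are too narrow. In neurons it had 1 UMI in each library, too few to compare. A 3′ count need not see the mutation, so this value does not check the genotype.

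Neurons made up a smaller share of the cftr_het library than of the WT library. They were 11.2% of WT cells (828 of 7413, 10.5% to 11.9%) and 5.63% of cftr_het cells (420 of 7461, 5.12% to 6.18%), a ratio of 0.504 (0.447 to 0.567). Neural progenitors or radial glia, the dividing and glia-like cells of the brain, were 3.55% in WT and 2.02% in cftr_het, a ratio of 0.570 (0.464 to 0.699). Oligodendrocytes or Schwann cells, the myelinating glia, were 1.01% and 0.925%, with a ratio of 0.914 whose interval of 0.649 to 1.28 includes 1. Photoreceptors were 1.96% and 1.49%, a ratio of 0.761 (0.589 to 0.981), and retinal pigment epithelium 17 and 38 cells, a ratio of 2.22 (1.22 to 4.196). The neurons lay in 2 clusters. Cluster 3, led by elavl3 and tuba1c, held 658 WT and 387 cftr_het neurons. Cluster 27, led by grid1b, scg2b, elavl4 and snap25a, held 170 and 33. A neuron sub-cluster of 96 WT and 53 cftr_het cells had a median of 710 UMIs. It was led by genes of other tissues, such as myhz1.1, ttn.1 and ela2. Another, of 10 and 4 cells, had olig1 and sox10 among its leading genes. The class may thus hold cells or RNA of other types. The first of these sub-clusters entered the setting that weights sub-clusters alike, which used 11 of 15, each with at least 10 cells per library.

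Outside the nervous system, epithelial and immune classes stood apart in both directions. Basal epidermis held 163 of 7413 WT and 369 of 7461 cftr_het cells, a ratio of 2.25 (1.87 to 2.72). Enterocytes were 0.553% and 1.35%, a ratio of 2.45 (1.69 to 3.61), and hair cells or their support cells 27 and 57 cells, with an interval of the ratio of 1.31 to 3.45. Neutrophils were 2.78% and 4.46%, a ratio of 1.61 (1.35 to 1.92), while macrophages or microglia were 5.71% and 3.74%, a ratio of 0.655 (0.561 to 0.764). Skeletal muscle was 5.25% and 7.18%, a ratio of 1.37 that turned to 0.911 at clustering resolution 0.5 and to 0.868 at resolution 2. Chondrocytes, endothelial cells, exocrine pancreas, iridophores, xanthophores and smooth muscle or mural cells had ratio intervals that include 1. Dissociation and cell recovery can set all of these shares.

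A pair of clusters came almost wholly from 1 library, and such a cluster may be that library and not a cell type. The lens cluster held 281 WT and 4 cftr_het cells, and 17.0% of its WT UMIs were exocrine pancreas markers. It showed 9 of 11 lens markers and was led by crystallin genes such as crybb1 and cryba4. The unnamed cluster 4 held 7 WT and 598 cftr_het cells with a median of 997 UMIs in cftr_het, and was led by the cardiac genes nppb, cmlc1, myl7 and nppa together with chia.2. The unnamed clusters took 25.8% of cftr_het cells and a smaller share of WT cells, 1482 of 7413. This difference of 5.80 points was smaller than the 7.92 points of cluster 4 alone, so it rests on that cluster. The shallow unnamed cluster 2 went the other way, with 676 WT and 372 cftr_het cells, a ratio of 0.547 (0.480 to 0.621).

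**Figure D1:**
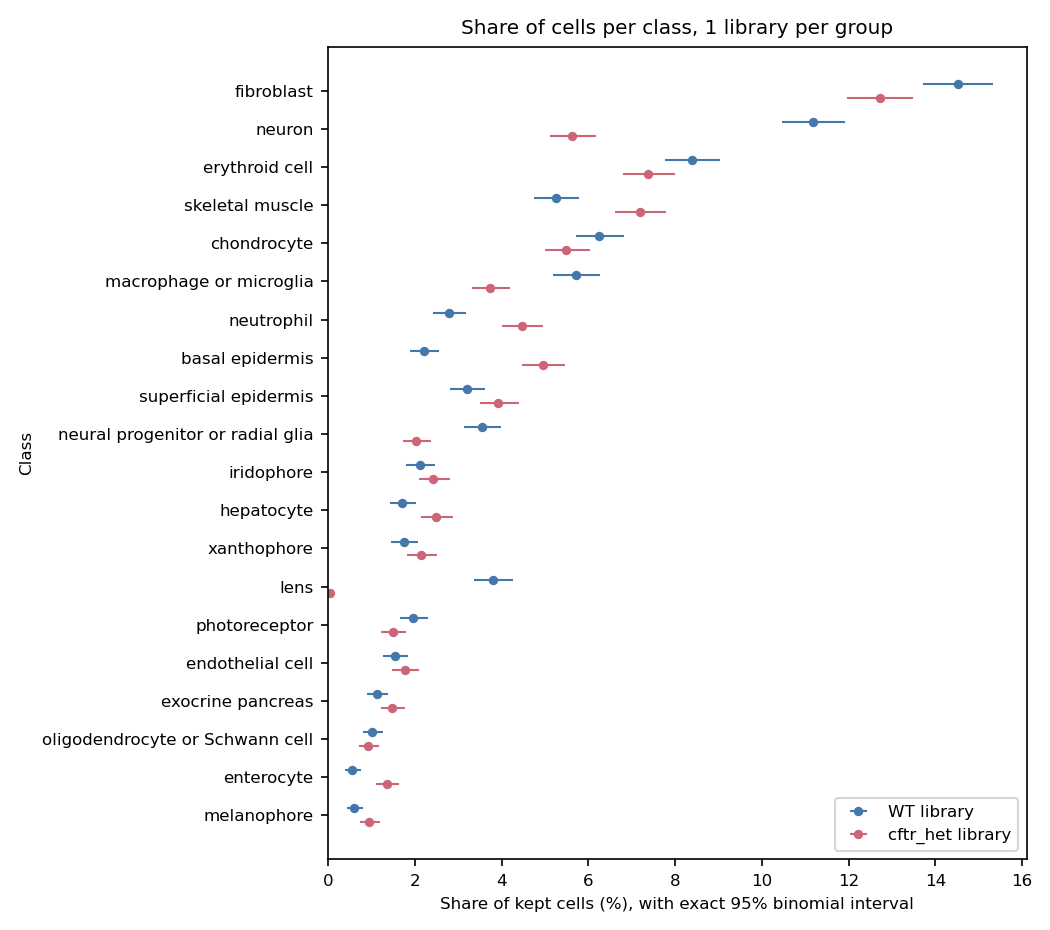
Share of kept cells in each named class with at least 100 cells over both libraries, in percent, with exact 95% binomial intervals, for the WT library and the cftr_het library. Neurons take 11.2% of WT and 5.63% of cftr_het cells, and the lens class holds 281 WT and 4 cftr_het cells.

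Within the neuron class, the genes with the largest differences were carried by few cells, and dbh, slc6a2, th, galn, prl and ins were among them. Noradrenergic genes were lower in cftr_het. The dopamine beta-hydroxylase gene dbh had 107 UMIs in 7 WT neurons and none in cftr_het, at least 17.3-fold lower, or 11.5-fold without the richest cell. The noradrenaline transporter gene slc6a2 had 67 UMIs in 7 WT neurons and none in cftr_het, at least 10.8-fold lower, or 6.13-fold without the richest cell. The tyrosine hydroxylase gene th had 51 UMIs in 7 WT neurons and 1 in cftr_het, a ratio with an upper limit of log2 -2.08. Neurons with dbh and also th or slc6a2 numbered 6 in WT and 0 in cftr_het. The 7 WT neurons with dbh are too few to show a difference in their share, because the interval of the ratio of cells, 0 to 1.37, includes 1. Over all cells, 14 WT and 3 cftr_het cells had a dbh UMI, a ratio of 0.213 (0.0392 to 0.763). Of the 114 dbh UMIs of all WT cells, 107 lay in the 7 neurons, so the other carriers held very few. In such cells free RNA cannot be told from expression, so this interval may be too narrow. Cells with at least 5 dbh UMIs numbered 5 in WT and 0 in cftr_het. In cftr_het, 1 kept cell outside the neuron class had dbh with th or slc6a2. Cells with slc6a2 numbered 62 and 41, a ratio of 0.657 (0.432 to 0.991), and with th 21 and 18, a ratio of 0.852 (0.428 to 1.68). For ddc (59 and 50 cells) and slc18a2 (31 and 35) the interval of the ratio over all cells also includes 1.

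Peptide and hormone genes went in both directions. The galanin gene galn had 247 UMIs in 7 WT neurons and none in cftr_het, at least 39.9-fold lower, or 7.10-fold without the richest cell. The gut peptide gene pyya had 746 and 16 UMIs (log2 ratio -4.45, -7.11 without each library's richest cell), and the kisspeptin gene kiss1, a leading gene of a neuron sub-cluster, 92 and 2 (-4.16, -5.22). The natriuretic peptide gene nppal had 74 and 1 (-4.59, -5.02). The pituitary hormone genes prl, pomca and cga had 465, 358 and 124 UMIs in 1, 2 and 3 WT cells of the neuron class and none in cftr_het. The insulin gene ins had 3797 UMIs in cftr_het, of which 3796 were in 1 cell, and none in WT. The glucagon gene gcgb (2 and 103 UMIs) and insl5a (157 and 2) likewise rested almost wholly on 1 cell, and the odorant receptor gene or115-12 had its 101 UMIs in 1 WT cell. Cells so rich in a pituitary or pancreatic hormone gene may be endocrine cells that clustered with neurons. The values of these hormone genes need not be differences within neurons.

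Other genes higher in cftr_het neurons were dlx2a, foxg1a, zfpm2b, pnoca and s100z. Of these, dlx2a, zfpm2b and s100z are leading genes of neuron sub-clusters, so the mix of sub-clusters enters their values. The homeobox gene dlx2a of GABAergic precursors had 37 and 101 UMIs (log2 ratio 2.48, interval 1.94 to 3.08), and the telencephalic gene foxg1a 26 and 47 (1.89, 1.18 to 2.65). The cofactor gene zfpm2b had 41 and 64 (1.68, with an upper limit of 2.29). The prepronociceptin gene pnoca had 27 and 109 (3.04, but 1.78 without the richest cells), and s100z had 137 and 262 (1.98, 2.47). The ferritin-like genes fthl28 and fthl31, also leading genes of a sub-cluster, were at 2.52 and 1.64, but at 1.00 and 0.92 without the richest cells. The genes zgc:101731, ndufa4l2a and si:ch211-196h16.12 complete the higher group, at 1.91, 5.84 and 7.38, the last of them in 2 cftr_het neurons and at 6.26 without the richest cells. Of the 24 named neuron genes, 21 were carried by fewer than 20 cells of the higher library and 15 had over 50% of their UMIs in 1 cell. As possible background, gcga, agt and chia.2 were higher and hsd11b2, wu:fj16a03 and BX322618.1 lower.

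Genes carried by at least 20 neurons, chosen after their values were seen, pointed to smaller differences. Lower in cftr_het were cep170b, of a centrosomal protein family, with 77 UMIs in 68 WT neurons and 3 in cftr_het (log2 ratio -3.42), the synaptotagmin gene syt5b with 112 and 10 (-2.38, -3.36 without the richest cells), the chromogranin gene chgb of secretory granules with 112 and 5 (-3.31, -2.70), and the calcium binders pvalb6 (-3.45) and calb2a (-2.51). The adenylate cyclase gene adcy2a was at -2.34 and the kinase gene gsk3bb at -2.35. Higher were the Wnt pathway factor lef1, with 179 UMIs in WT and 211 in cftr_het (1.28), the sensory and habenular factor pou4f1 (1.36) and the midbrain factor en2a (1.26). Of these genes, lef1, pou4f1, en2a, syt5b and calb2a are leading genes of neuron sub-clusters, so the mix of sub-clusters enters their values. Over all 6046 genes with at least 50 UMIs the median log2 ratio was -0.03.

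**Figure D2:**
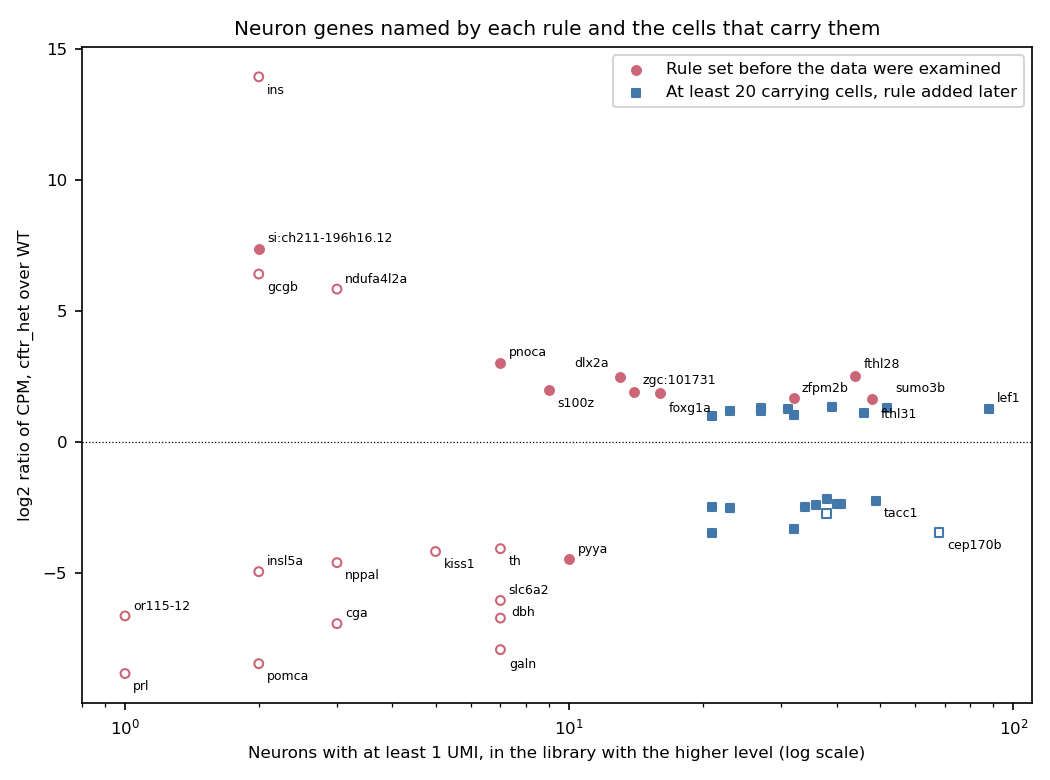
The log2 ratio of CPM in neurons, cftr_het over WT, against the number of neurons with a UMI of the gene in the library with the higher level (log axis), for genes named by each rule. Open symbols have 3 or fewer UMIs in a library, so that their height depends on the prior of 0.5 UMIs; of 24 genes named by the rule set before the data were examined, 21 lie below 20 cells.

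Transmitter, synaptic and channel lists were lower in summed UMIs of cftr_het neurons, and most of these medians moved with the weighting of neuron sub-clusters. The dopamine and noradrenaline list had the lowest median, a log2 ratio of -1.81 (interval -2.58 to -1.06), below all 10000 random lists, with 11 of 13 measured members lower. The same 6 WT neurons held dbh with th or slc6a2, so these members are not independent. Besides dbh, slc6a2 and th, its lower members included the dopamine receptor gene drd2b (-1.03), the monoamine oxidase gene mao (-2.15) and otpa (-0.95, -1.59 without the richest cells), a factor of dopaminergic neurons. The neuropeptide list was at -1.21 (-1.36 to -0.92, percentile 0.0), with 16 of 19 lower, among them vipb (-1.01), vgf (-1.21), scg2b (-0.81) and tac1 (-2.70, -3.97 without the richest cells). Its median was -0.55 with clusters weighted by cells, -0.57 with sub-clusters weighted alike and -1.84 without the richest cells. The serotonin list was at -1.05 (percentile 0.075), with 6 of 9 lower, among them htr2cl1 (-1.06) and htr4 (-2.90). It was at -0.31 with clusters weighted by cells, at -0.33 with sub-clusters weighted alike, and reversed to 0.29 without the GABAergic sub-cluster.

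The GABA and glycine list was at -0.46 (-0.70 to -0.33, percentile 0.02), with 23 of 25 lower, including the GABA-synthesis genes gad1b (-1.36) and gad2 (-0.98) and the GABA transporter gene slc6a1b (-1.08). The glutamate list was at -0.34 (percentile 0.42), with 24 of 30 lower, while the vesicular transporter gene slc17a6a was higher (1.24). The synaptic vesicle and SNARE list was at -0.32 (percentile 0.1), with 21 of 31 lower, including snap25a (-0.64), syt1a (-0.54) and rims2a (-1.21). Voltage-gated channels were at -0.38 (percentile 0.07), with 25 of 31 lower, such as the calcium channel gene cacna1g (-1.25). Candidate genes of attention-deficit hyperactivity disorder were at -0.29 (-0.55 to -0.17, percentile 1.06), with 17 of 25 lower. Their members snap25a, dbh and slc6a2 also sit in the lists above, and the latrophilin gene adgrl3.1 was at -0.38 and ptprfb at 0.30. The medians of these 5 lists turned positive when neuron sub-clusters were weighted alike, to 0.05 for GABA and glycine, 0.45 for glutamate, 0.24 for synaptic vesicle and SNARE, 0.29 for channels and 0.10 for the disorder candidates. The dopamine and noradrenaline list was then at -1.43, but at -0.52 without the GABAergic sub-cluster, -0.92 with clusters weighted by cells, -0.95 with members of at least 100 UMIs and -0.67 with members of at least 1 UMI. The sub-cluster left out held 148 WT and 20 cftr_het cells, while another named GABAergic held 23 and 22. Leaving it out is therefore not a test of GABAergic neurons as such.

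Shares of neurons with a UMI, thinned to 1000 UMIs, were lower in cftr_het for scg2b and higher for slc17a6a, while snap25a and gad2 were lower with overlapping intervals. The thinned sets were 575 WT and 290 cftr_het neurons, after 253 and 130 shallower ones were left out. The SNARE gene snap25a was seen in 28.3% of WT (24.7% to 32.2%) and in 58 of 290 cftr_het neurons (15.6% to 25.1%), against 0.665% and 0.107% of thinned fibroblasts. The unthinned shares were 32.7% and 26.2%. The secretogranin gene scg2b was seen in 17.0% and 7.59% (20.5% and 12.1% unthinned), gad2 in 8.0% and 4.14% (10.1% and 6.90%), and slc17a6a in 2.09% and 6.55% (4.11% and 9.05%), with at most 0.0950% of fibroblasts. The GABA receptor gene gabbr2 was seen in 22.4% and 25.2% (29.95% and 30.0% unthinned), and vipb, whose summed level was lower, in 1.57% and 1.72% (1.81% and 1.43%), with overlapping intervals in both genes. Median depth was 1294.5 and 1319 UMIs in neurons and 5301 and 4748 in fibroblasts.

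Among stress and housekeeping lists, the immediate early list was lower and the ribosomal list higher in cftr_het neurons. Cytosolic ribosomal proteins were at 0.26 (0.24 to 0.28, percentile 99.98), with 78 of 81 members higher, such as rplp1 (0.32). This list was at 0.00651 with sub-clusters weighted alike, 0.0772 at resolution 2 and 0.0804 with clusters weighted by cells. Immediate early and dissociation genes were at -0.70 (percentile 0.0), with 24 of 28 lower, including fosab (-0.79) and dusp5 (-1.25). Thinned shares of neurons went both ways, with overlapping intervals for each gene. Of 575 WT and 290 cftr_het neurons, 153 and 64 had fosab and 43 and 12 had dusp5. Shares were higher in cftr_het for atf3 (195 and 112 neurons), jun (210 and 110) and klf6a (104 and 66). After thinning, fosab, atf3, jun and klf6a were each seen in a larger share of fibroblasts than of neurons. They may not be neuronal in origin. The immediate early list was at -0.0853 with the marker gate, -0.26 with sub-clusters weighted alike, -0.32 with free RNA subtracted and -0.37 with clusters weighted by cells. Heat shock genes were at 0.24 (percentile 95.9), with hsp70l at 38869 CPM in WT and 38499 in cftr_het, and the unfolded protein response was at 0.20 (percentile 96.3), with hspa5 at 0.39. Heat shock was at 0.0116 with the marker gate and the unfolded protein response at 0.0492 with sub-clusters weighted alike. Glycolysis was at -0.32 (percentile 0.11; -0.0319 with sub-clusters weighted alike), mitochondrially encoded genes at -0.26 (percentile 1.16) and the nuclear-encoded respiratory chain at -0.08 (percentile 9.67). Astroglia and radial glia genes, markers of other cells, were at -0.56 (percentile 0.705), with fabp7a at -2.41, and this list was at -0.12 with sub-clusters weighted alike. The myelin list was at -0.81 (percentile 0.21), but its median was 0.38 without possible background genes.

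The fluid and chloride transport list, which holds cftr's relatives in function, was at -0.45 (percentile 1.62), with 17 of 19 lower, led by the sodium pump gene atp1b1b (-1.12). The list was at -0.20 with sub-clusters weighted alike. Its member atp1b1b is a leading gene of the GABAergic sub-cluster with 148 WT and 20 cftr_het cells, so the mix of sub-clusters enters its value. Acetylcholine was at -0.37 (percentile 8.86; 0.13 with sub-clusters weighted alike), adenosine and purine at -0.27 (percentile 18.8; 0.0458 with the marker gate and 0.00961 with doublets kept), interferon response at -0.40 (percentile 13.8) with 4 members, and inflammation at -0.12 (percentile 33.8). The inflammation list turned to 0.19 with the stricter filter, 0.33 with doublets kept and 0.0540 without the richest cells. Neurotrophin and growth was at -0.04 (percentile 35.5), with the growth-associated tubulin gene tuba1c at 0.60. Circadian clock was at 0.00 (percentile 64.2), glucocorticoid response at 0.01 (percentile 61.2), with igfbp1b at 2.24 (0.55 without the richest cells), and p53 and apoptosis at -0.06 (percentile 26.9). Proliferation was at 0.34 (percentile 98.6), oxidative stress and metal response at 0.22 (percentile 96.5) and the gastrula-stage genes at 0.49 (-0.15 to 0.88, percentile 98.4) with 6 members. These 3 lists also changed sign with the processing. Proliferation was at -0.56 at resolution 2 and -0.17 with the marker gate, and oxidative stress and metal response at -0.15 with sub-clusters weighted alike. The gastrula-stage genes were at -0.0216 without the richest cells and -0.54 with members of at least 1 UMI. MHC class I and antigen processing had 2 measured members in neurons, too few for a median.

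**Figure D3:**
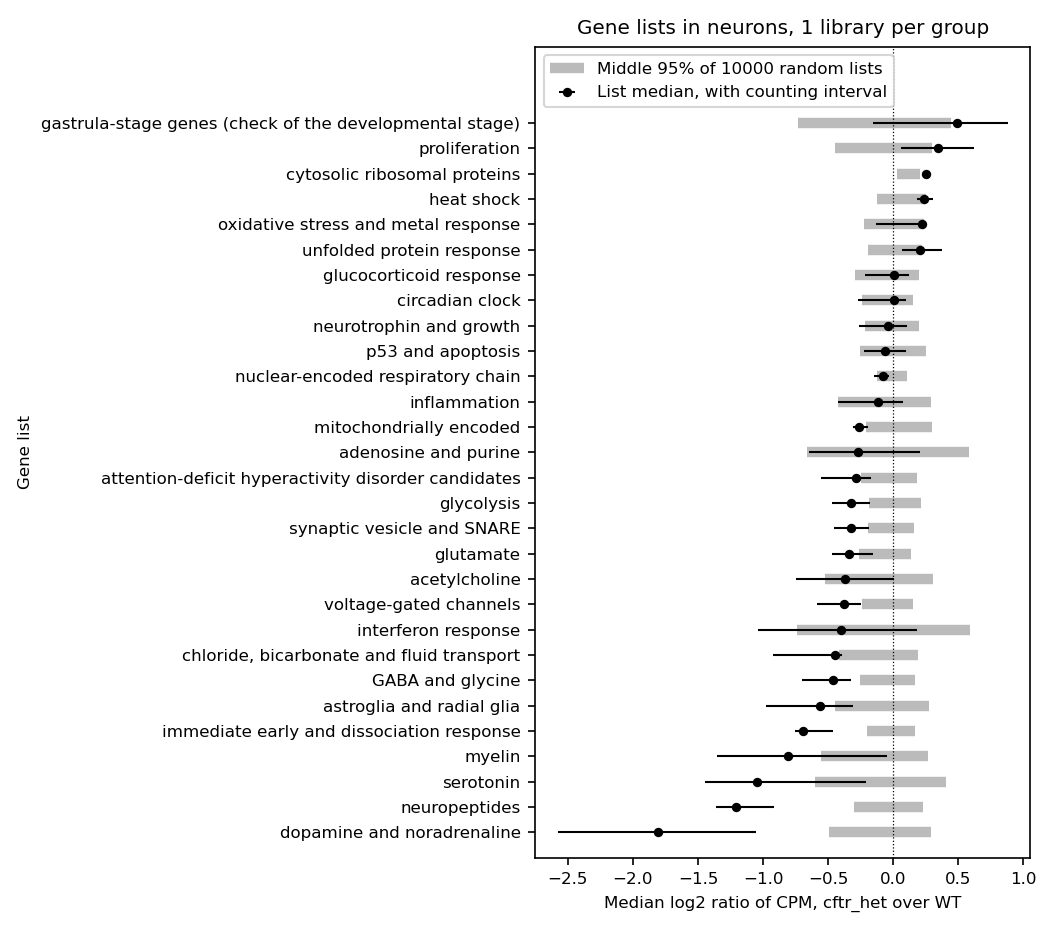
Median log2 ratio of CPM in neurons, cftr_het over WT, for each gene list (points) with its counting interval, over the middle 95% of 10000 random lists matched on mean CPM (grey bars). The dopamine and noradrenaline list lies lowest at -1.81, and the cytosolic ribosomal proteins lie at 0.26.

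In neural progenitors or radial glia, cell cycle genes were lower and inflammation genes higher in summed UMIs of cftr_het. All 24 measured proliferation genes were lower, with a median log2 ratio of -1.30 (-1.65 to -1.12, percentile 0.0) and -1.50 without each gene's richest cell. The proliferation marker mki67 had 43 UMIs in WT and 4 in cftr_het (-2.33), the replication genes pcna 161 and 35 (-1.25) and mcm6 58 and 10 (-1.54), and the mitotic kinase gene aurkb 30 and 3 (-2.18, -3.09 without the richest cells). After thinning, 17 of 241 WT and 3 of 135 cftr_het cells, 7.05% (4.16% to 11.05%) and 2.22% (0.461% to 6.36%), had at least 10 UMIs of the list, and these intervals overlap. Unthinned, these were 34.6% and 21.2%. Thinned shares with pcna were 5.39% and 5.19%, against 6.41% and 6.13% of erythroid cells. Erythroid cells are no clean reference for pcna, since it is a leading gene of erythroid cluster 41, with 30 WT and 25 cftr_het cells. Thinned shares with mki67 were 1.66% and 0.0%, with overlapping intervals, and no thinned erythroid cell had mki67. All 12 inflammation genes were higher, with a median of 1.47 (percentile 100.0) that was 0.69 without the richest cells. The transcription factor gene cebpb had 295 and 448 UMIs (1.54, but 0.00 without the richest cells), and the chemokine gene cxcl8a 29 and 60 (1.98, but 0.80), so a few cells decide these values. Thinned shares with cxcl18b were 6.22% and 3.70%, with nfkbiab 16.6% and 15.6%, and with cxcl8a 1.24% and 4.44%, so these shares went both ways. Erythroid cells were at 2.56% and 3.48% for cxcl18b, 10.1% and 8.18% for nfkbiab and 0.183% and 2.25% for cxcl8a. The cftr_het share with cxcl18b was thus near that of erythroid cells. The unfolded protein response was at 0.49 (percentile 99.9), with the stress factor ddit3 at 1.95 and xbp1 at 1.06. Thinned shares of progenitors went both ways, with overlapping intervals for each gene. They were 5.809% and 11.85% for ddit3 and 10.79% and 16.30% for xbp1. The chaperone gene hspa5 was lower, at 18.67% and 13.33%, as was atf4b, in 62 of 241 WT and 27 of 135 cftr_het cells. Thinned erythroid cells also had more ddit3, in 4.40% and 10.22%, and more xbp1, in 10.1% and 23.1%. The difference in these genes is thus not particular to progenitors. Heat shock genes were at -0.19 (percentile 0.06) and mitochondrially encoded genes at -0.37 (percentile 0.0).

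The named genes of this class were less evenly carried. The cerebellar progenitor factor atoh1c had 66 UMIs in 11 WT cells and 1 in cftr_het (log2 ratio -4.53, -5.54 without the richest cells), enc3 68 and 5 (-2.70), and sparcl1 119 and 4 (-3.79, -2.76 without the richest cells). Higher were npr3, pkd1b and timp2b, at 7.37, 5.63 and 5.26, but 128 of 129 cftr_het npr3 UMIs were in 1 cell and the values without the richest cells were 2.52, 2.32 and 2.79. TMM scaling lowers all values of this class by 0.19.

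Over all cells, the lists of neuronal genes were lower in cftr_het, which mixes the smaller share of neurons with levels inside cells. GABA and glycine were at -1.16, synaptic vesicle and SNARE at -1.02, voltage-gated channels at -0.97, glutamate at -0.95 and neuropeptides at -1.95, each below all 10000 random lists. The disorder candidates were at -0.55, also below all of them. The heart genes nppa, myl7, cmlc1 and nppb were higher, with 0, 5, 6 and 21 UMIs in WT and 475, 835, 982 and 817 in cftr_het. At least 311 cftr_het cells had a UMI of each, and nppa was at least 148-fold higher. Part of this is possible background, since the unnamed cluster 4 held 1465 of the 3808 cftr_het UMIs of 7 cardiac markers, while fibroblasts had 6 of these UMIs in WT and 171 in cftr_het, erythroid cells 7 and 115 and neurons 8 and 91. Others at the high end were ins (9.10, with 3796 of its 3816 cftr_het UMIs in 1 cell) and ENSDARG00000101964 (7.70, 5.68). Lower were zgc:113057, with 291 and 11 UMIs in 196 and 11 cells (-4.76), pyya (-5.16, -5.87 without the richest cells), galn (-6.34, -5.48), epd (-5.07, with 1930 of 2206 WT UMIs in 1 cell), pomca (-5.21, -2.08) and prl, with 474 UMIs in WT and none in cftr_het. TMM scaling raises all values over all cells by 0.10.

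Erythroid cells of cftr_het had more of the ferritin-like fthl28, with 220 and 2190 UMIs (3.66, 3.46 to 3.87), of fthl31 (2.51) and of the metallothionein gene mt2 (248 and 1100 UMIs), each in at least 161 cells. Without the richest cells, fthl28 had a log2 ratio above 0.3 in 12 of 15 classes examined, fthl31 in 15 of 16 and mt2 in 15 of 16. They were possible background in 53.3%, 62.5% and 56.25% of these classes. The nuclease gene dnase1l4.1 was lower (-1.81), as were the clock gene cry1b (-1.45) and si:ch73-335l21.1 (-1.43). Macrophages or microglia of cftr_het had more cd74a, of the MHC class II invariant chain, with 21 and 107 UMIs (2.92), and less si:dkey-7i4.24, with 730 and 18 (-4.70), and BX323593.1, with 58 and 2 (-3.95, -4.56 without the richest cells). The higher ved and arf4b and the lower ccl38a.4 had over 50% of their UMIs in 1 cell. Neutrophils had more chka, the choline kinase gene, in 123 cells (3.53), more capga (3.74) and chsy3 (3.47, 4.48 without the richest cells), and less BX323593.1 (-2.35) and brinp3a.2 (-2.13). The lower hmox1a (-2.41) was at -0.54 without the richest cells. Neutrophil clusters 7, 40 and 45 held 189, 12 and 5 WT and 244, 49 and 40 cftr_het cells, so the mix of clusters can enter neutrophil values. TMM scaling lowers erythroid values by 0.11 and raises neutrophil values by 0.16.

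Fibroblasts of cftr_het had more isg15, an interferon-induced ubiquitin-like gene, with 28 and 195 UMIs (3.21), and more ociad2 (2.12), and less of the acute-phase gene saa, with 2705 and 49 UMIs in 54 and 29 cells (-5.34). In the same class enam was higher (2.21, 2.80 without the richest cells), and the lower epd (-9.90) and ggctb (-5.41) had over 90% of their UMIs in 1 WT cell and were at -3.26 and -1.78 without it. Superficial epidermis had more of the keratin gene krt1-19d, with 1 and 627 UMIs in 1 and 20 cells (8.62) and 329 of the cftr_het UMIs in 1 cell, while zgc:172053 and a further gene rested on 1 cell. The genes rem2 (-1.75), si:dkeyp-51b9.3 (-1.91) and ponzr4 (-1.50) were lower there. In basal epidermis the caspase gene caspb was higher, with 58 and 434 UMIs (1.82), as was tkta, with 568 UMIs in 16 cells against none, at least 89.8-fold or 57.7-fold without the richest cell, and CT573383.1 (2.05, 3.41 without the richest cells). The genes rem2 (-3.07), cep170b (-1.60) and the fibronectin gene fn1a (-1.47) were lower. Chondrocytes had more CR855311.1 (1.59), cyp4t8 (1.38) and camsap2a (1.31), and less aplnra (-2.56) and si:ch73-299h12.6 (-1.42). The collagen gene col10a1a of hypertrophic cartilage had 97 UMIs in 4 WT chondrocytes and none in cftr_het, at least 26.2-fold lower, or 6.75-fold without the richest cell. TMM scaling lowers superficial epidermis by 0.11.

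In muscle, vessels and pigment cells the named genes were as follows. Skeletal muscle of cftr_het had more rab11fip4a (3.06), more of the adhesion gene ncam2, with 70 and 489 UMIs (2.26), and more CU914776.1 (1.75), and less tnni2a.2 (-2.06), myh7l (-1.70) and cox6a2 (-1.47). Endothelial cells had more of the mural-cell gene rgs5a, with 8 and 167 UMIs (4.26, 5.43 without the richest cells), more ptgs2a (2.98) and npb (2.57, 0.69), and less osr2 (-2.85, -3.54), zgc:158423 (-2.98, -2.08) and slc7a3a (-2.93, with 42 of 55 WT UMIs in 1 cell). Iridophores had more drp2 (2.11), rgs16 (1.77) and rnf13 (1.59), and less FQ976914.1 (-2.85) and il4r.1 (-1.45). There BX908782.2 was at -2.97 but at 1.00 without the richest cells. Xanthophores had more isg15, with 3 and 59 UMIs (3.74, 4.76 without the richest cells), more arf4b (5.38) and myhz1.3 (3.57, 2.94), and less slc38a11 (-1.91), cnp (-1.79) and gsto2 (-1.54), and TMM scaling lowers these by 0.14. By the log2 cut of 0.3, arf4b was higher in 5 and lower in 1 of 6 classes examined. The muscle gene myhz1.3 was higher in 13 and lower in 2 of 15, and possible background in 80% of them. Neither is thus particular to xanthophores.

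Organ and sensory classes held few cells. Exocrine pancreas cells had a median of 2258 UMIs in WT and 30768.5 in cftr_het, and TMM scaling raises their values by 0.50. There si:ch73-44m9.5 (3.52, 4.64 without the richest cells), selenom (1.82) and timm17a (1.32) were higher, and zgc:193726 (-5.93, -6.76), BX855618.1 (-4.84, -6.55) and clec16a (-2.45) lower. Hepatocytes had less of the apolipoprotein gene apoa1a (-1.49, -0.84 without the richest cells), si:dkey-35h6.1 (-1.43) and si:dkeyp-73d8.6 (-1.39) and more zgc:110286 (4.99, 5.74). The higher si:dkey-78l4.2 and si:ch211-196h16.12 were each in 1 cftr_het hepatocyte. Photoreceptors had less glula, the glutamine synthetase gene of glia (-2.59), and less of the cone transducin gene gngt2a (-2.55, -1.74). They had more fthl28 (2.94, 1.88) and calb2a (4.79, 2.48), while pvalb5 (4.03) and ttn.1 (-1.90) turned to -3.18 and 0.90 without the richest cells. Oligodendrocytes or Schwann cells had more of the myelin protein zero gene mpz, with 94 and 278 UMIs, more flj13639 (2.71) and cryabb (1.75), and less ifi46, with 94 and 15 (-2.37), ctnna2 (-2.30) and zgc:153704 (-1.75). TMM scaling lowers these by 0.18. Over every class other than all cells, 63 of 120 named genes were carried by fewer than 20 cells.

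RNA of other tissues in neurons differed between the libraries. Exocrine pancreas markers took 3.27% of neuron UMIs in WT and 1.90% in cftr_het, a ratio of 0.581 (0.571 to 0.591), and haemoglobin 0.0623% and 0.0296%. Skeletal muscle markers took 2.83% and 2.87%, hepatocyte markers 0.0698% and 0.0655%, and lens crystallins 0.0255% and 0.0186%. Enterocyte markers took 0.00789% and 0.0516%, and cardiac muscle markers 0.000461% and 0.0108%. The median neuron had 1294.5 UMIs in WT, with 2.65% of them mitochondrial, and 1319 in cftr_het, with 2.22%.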

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

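No paired analysis was possible because there was 1 library per group. The settings that leave out richest cells, weight sub-clusters alike, leave out the GABAergic sub-cluster or leave out clusters of mostly 1 library were chosen after seeing the data, and all others before. Where a value below moved or reversed, the cause was not tested. The 24 named neuron genes kept their direction in every setting that gave a value. They had been chosen for extreme ratios with the same direction in neuron clusters, so the kept direction is a weak check. Only 18 of the 24 had a value with richest cells left out, and 6 were at the floor. The cftr ratio stayed between 0.794 and 1.09 in the settings tried, within its interval. Among the share of cells per class, the neuron ratio stayed below 1 throughout, at 0.410 with cells named one by one and 0.570 with the marker gate, and at 0.515, 0.495, 0.484, 0.488, 0.518 and 0.527 in the others. Naming one by one called 57.5% of WT cells exocrine pancreas and 44.7% of cftr_het cells skeletal muscle, and only 63 and 26 cells neurons. Its values are therefore weak, and the cause was not tested. Genes with few UMIs, and classes with few cells, limit what can be seen at this depth.

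With cells named one by one the photoreceptor ratio reversed to 1.28. The skeletal muscle ratio reversed to 0.911 at resolution 0.5 and 0.868 at resolution 2. With the marker gate the median of the neuron log2 ratios was -0.10, GABA and glycine -0.78 and synaptic vesicle and SNARE -0.61, while myelin reversed to 0.38, the nuclear-encoded respiratory chain to 0.0209 and proliferation to -0.17. At resolution 2 the neuron median reversed to 0.00405, myelin to 0.10 and proliferation to -0.56. With the stricter filter myelin reversed to 0.29 and proliferation to -0.13.

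With TMM scaling the median of the neuron log2 ratios was -0.00762. In progenitors the immediate early list reversed to -0.0186 and p53 to -0.0687, and over all cells myelin reversed to 0.0679, immediate early to 0.0015, inflammation to 0.0506, proliferation to 0.0039 and ribosomal proteins to 0.0612. With median-ratio factors p53 in progenitors reversed to -0.0234. With totals without ribosomal, mitochondrial and haemoglobin genes the neuron median reversed to 0.00415, and with a prior of 2 UMIs it was -0.00186. With classes weighted alike the whole-library median was -0.0453, and over all cells the nuclear-encoded respiratory chain reversed to -0.0271 and proliferation to 0.0121.

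With clusters weighted by cells the median of the neuron log2 ratios reversed to 0.057 and glutamate to 0.0558, and dopamine and noradrenaline was -0.92, GABA and glycine -0.20, synaptic vesicle and SNARE -0.0985 and the disorder candidates -0.11. With sub-clusters weighted alike the neuron median reversed to 0.0846, GABA and glycine to 0.0489, glutamate to 0.45, synaptic vesicle and SNARE to 0.24, the disorder candidates to 0.10, voltage-gated channels to 0.29 and myelin to 0.0366. Without the GABAergic sub-cluster the neuron median reversed to 0.0551, serotonin to 0.29, glutamate to 0.14 and the respiratory chain to 0.0468, and dopamine and noradrenaline was -0.52, GABA and glycine -0.12, synaptic vesicle and SNARE -0.0655 and the disorder candidates -0.0387.

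With free RNA subtracted the median of the neuron log2 ratios was -0.37, GABA and glycine -1.003, synaptic vesicle and SNARE -0.89 and the disorder candidates -0.81, while the respiratory chain reversed to 0.83 and mitochondrially encoded genes to 0.0194. This subtraction took the free profile as 79.4% of WT and 31.0% of cftr_het neuron UMIs, and gave 10.71 for cytosolic ribosomal proteins, 2.39 for the glucocorticoid response and 1.75 for oxidative stress and metal response, so its values are extreme and unequal between libraries. Without possible background genes the neuron median was -0.0197 and myelin reversed to 0.38. With members of at least 100 UMIs dopamine and noradrenaline was -0.95 and myelin reversed to 0.22, and with members of at least 1 UMI these were -0.67 for dopamine and noradrenaline and a reversed -0.054 for proliferation. With richest cells left out the neuron median was -0.0671, the progenitor lists of immediate early genes and p53 reversed to -0.14 and -0.0383, and BX908782.2 in iridophores, pvalb5 and ttn.1 in photoreceptors reversed to 1.00, -3.18 and 0.90. Of 91 named genes of other classes with a value, 68 stayed the same in this setting, 20 moved and 3 reversed.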

Other observations

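Several genes stood apart in many classes at once. Here a class counted as higher or lower only beyond a log2 ratio of 0.3 either way. A gene stood apart if 80% of its classes did so in 1 direction, with a median beyond 0.7. Of 6551 genes examined in 17 classes without each gene's richest cell, 14 had levels of their own that differed widely, 66 were possible background RNA and 11 lay between. The centrosomal gene cep170b was lower in cftr_het in 10 of 10 classes, with a median log2 ratio of -2.06, and si:ch73-299h12.6 in 9 of 11 (-1.40). Higher were ece2b in 13 of 14 classes (0.89, lowest value 0.21) and the p53 target cdkn1a in 12 of 15 (1.01). The metallothionein gene mt2, one of those between, was higher in 15 of 16 (2.13) and possible background in 56.25% of the 16. Among possible background genes, the exocrine protease gene cela1.3 was lower in 16 of 16 classes (-1.97), while chia.2 was higher in 14 of 14 (3.61) and the lysozyme gene lyz in 17 of 17 (2.08).

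All tests below were chosen after the results were seen, though the totals without ribosomal, mitochondrial and haemoglobin genes were a setting fixed before. The share of neurons was smaller in cftr_het, with a ratio of 0.504. Dilution by clusters of 1 library is unlikely to account for it, since the ratio was 0.527 without them. A loss of head tissue as a whole, alike in its cell types, is also unlikely, since the retinal pigment epithelium had a ratio of 2.22 (1.22 to 4.196), with a lower limit of at least 0.822 in every setting and a neuron upper limit of at most 0.657. Photoreceptors were at 0.761, but at 0.962 (0.634 to 1.46) with the stricter filter and 0.908 (0.676 to 1.22) with cells thinned. Lens was at 0.0141, at 0.0852 at resolution 2 and at 0.157 with cells named one by one. Its cluster was lens-like by 9 of 11 markers, but it came almost wholly from WT and may reflect that library. A loss that differs between the cell types of the head stays open. With 1 library per group, the cftr genotype cannot be told from clutch or dissociation and was not tested.

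The genes dbh, slc6a2 and th were lower in cftr_het neurons. Whether few noradrenergic cells were caught by chance cannot be told, since the upper limit of the ratio of neurons with dbh was 1.37. Over all cells the dbh ratio was 0.213 (0.0392 to 0.763), but it also counts cells with very few dbh UMIs, which need not express it. Cells with at least 5 dbh UMIs numbered 5 in WT and 0 in cftr_het. Over all cells the ratio was 0.657 (0.432 to 0.991) for slc6a2 and 0.852 for th, with a th interval of 0.428 to 1.68 that includes 1. Free RNA in WT droplets is unlikely, since 74.8% of WT neuron dbh UMIs lay in 3 cells. An effect of the cftr genotype stays open and was not tested.

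The synaptic, GABA, glutamate and channel lists were lower in cftr_het neurons, with -0.36 in the middle of the 4 medians. A different mix of neuron sub-clusters may account for this, since the middle value was 0.26 with sub-clusters weighted alike, though the sub-clusters were made from the same genes, so fewer such cells and lower levels within cells are not separable. Scaling by ribosomal and mitochondrial UMIs is unlikely, since the value was -0.32 without them. Whether cftr_het neurons held more free RNA cannot be told from marker genes of other tissues, because these went both ways. Haemoglobin, exocrine pancreas and skeletal muscle markers summed to 6.16% of WT and 4.79% of cftr_het neuron UMIs, a difference of -1.37 points. Of these, exocrine pancreas markers took 3.27% in WT and 1.90% in cftr_het. Enterocyte markers were higher in cftr_het, at 0.00789% and 0.0516%, as were cardiac muscle markers, at 0.000461% and 0.0108%. The cftr genotype was not tested and stays open.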
